A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

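RNA was sequenced from 12 Saccharomyces cerevisiae samples at 36 h, in 4 groups of 3 replicates. Strains YJ-04 (low SAM) and YJ-06 (high SAM) carried a bikaverin biosynthesis module, and strains YJ-08 (low SAM) and YJ-09 (high SAM) carried plasmid pRS416, per the labels. The labels do not say that the replicates are separate cultures, so each p-value measures only the spread between these samples, which may be technical. How the level of SAM was raised is not given in the sources used here. Samples were ground frozen, total RNA was taken with the RNAprep Pure Plant Plus kit and libraries were made with the Fast RNA-seq Lib Prep Kit V2, per the labels' protocols.

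The values used were FPKM (fragments per kilobase of gene per M reads), made by the authors in 2 tables, 1 for each pair of strains. The tools named are fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3, with genome build R64, per the submitters' processing notes. The strand setting, the annotation and any filter of the reads are not given in the sources used here. Columns were joined to samples by the strain and library name in the column headers and sample titles, because another label field gives other library numbers. All columns were used. The tables list 6845 (bikaverin) and 6818 (pRS416) features, of which 6755 are in both, and 706 identifiers written in another style were restyled to match. By identifier, 5944 and 5934 features (86.8% and 87.0%) were matched to the R64 reference, which gave their exonic length and coordinates. Of the genes in the lists tested, 1 was not matched.

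Depth was recovered from the values. FPKM multiplied by exonic length came in steps of 1 read, and 97.3% to 98.8% of the values under 1000 reads lay within 0.02 of a whole read. The scaling totals were 15.4 to 17.7 M per library in the bikaverin table and 40.7 to 45.1 M in the pRS416 table, and the matched genes held 95.3% to 104.7% of them, so the total used by the authors was not exactly the sum over these genes. Matched genes held 16.1, 16.4 and 17.8 M reads in the 3 bikaverin low-SAM libraries, 15.4, 15.0 and 16.2 M in the high-SAM ones, 40.6, 43.2 and 40.1 M in pRS416 low SAM and 41.5, 41.7 and 45.1 M in pRS416 high SAM. The 10 highest features took 9.85% to 12.6% of reads in the bikaverin table and 7.20% to 13.6% in the pRS416 table. For a gene of 1 kb, 3 reads correspond to 0.170 to 0.195 FPKM (bikaverin) and 0.0665 to 0.0737 FPKM (pRS416). A group with no read was given a smallest fold against 3 reads over its libraries, and a group with 1 to 3 reads a ratio with its exact 95% interval. These intervals and floors cover counting error only.

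Each pair was tested within its own table with limma 3.58.1 in R 4.3.3 (linear model with an intensity trend) on log2(FPKM + 1), for features with a mean of at least 1 FPKM over the 6 libraries, with no replicate block. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and adjusted p-values given below for genes are from this test. Fold changes are ratios of mean FPKM, and log2 fold changes are those of log2(FPKM + 1), which understate the change of genes at low levels. The difference between the pairs, (bikaverin high minus low) minus (pRS416 high minus low), was tested in 1 fit of all 12 libraries, so no level was compared across tables. Overlap of calls was tested with Fisher's exact test, one-sided for more overlap, and fold changes of the pairs were compared by Pearson's r and Spearman's rho. In addition, 47 lists of pathways, regulons, complexes and cell-type markers were fixed before the data were examined. They were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. A list of at least 4 tested members could be called. The camera test on the difference between the pairs was added after the first results had been seen.

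Named genes followed a fixed rule. SAM1, SAM2, SAH1, ADO1, MET6 and the genes of sulfate uptake and reduction were always named. For each pair, the 10 genes higher and the 10 lower of largest log2 fold change were named, among those called, with at least 10 FPKM in the higher group and no overlap between the 3 and 3 libraries (10% of random orders would show no overlap). Further named genes were up to 4 members of smallest p for each list in the text, the 5 largest and 5 smallest differences between the pairs, and the 10 genes with the largest change shared by both pairs. Genes with copies at 90% identity or more over at least 50% of their length, found with BLAST+ 2.17.0, were named as uncertain. Genes named outside the rule are said to have been chosen after their values were seen.

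The fits were tested on simulated data with 200 changed genes and a dispersion of 0.01. At a log2 change of 0.5, 1 and 2, the bikaverin fit recovered 73.1%, 97.0% and 100% of changed genes with 2.70% false calls, and the pRS416 fit recovered 77.3%, 100% and 100% with 3.16%. The fit of the difference recovered 99.2% of differences of at least 1, with 4.88% false calls. All simulated genes had the same dispersion. In the data the spread varied between genes, and 56.7% (bikaverin) and 77.5% (pRS416) of features were called, so these rates may not hold there. The list that was changed was called in both pairs, with 0 (bikaverin) and 1 (pRS416) other lists called. Genes were simulated independently of each other, so these counts say nothing about false calls of lists whose genes move together.

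Alternatives fixed in advance changed the pseudocount, the filter, the scaling (median ratios, quantiles), the prior variance, the replicate block, the libraries used and the correlation in the list test. Added later were limma voom on the recovered reads, protein-coding genes alone, and a fit without features near 0 in the high-SAM libraries of both pairs. Tests that need read counts from the authors were not run, because the tables used here hold FPKM. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statmod 1.5.0 and matplotlib 3.10.9.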

Results

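Transcriptomes were compared between strains of high and low level of S-adenosylmethionine (SAM), the methyl donor of most cellular methylation, to see which genes differ with the level of SAM. High-SAM strain YJ-06 was set against low-SAM strain YJ-04 among strains with an introduced module for bikaverin, a fungal polyketide pigment whose synthesis includes SAM-dependent O-methylation. High-SAM strain YJ-09 was set against low-SAM strain YJ-08 among strains with plasmid pRS416, a yeast shuttle vector with a URA3 marker. Values are mean ± SD in FPKM of 3 libraries per group, low SAM before high SAM.

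In the bikaverin pair, 10 of the 11 genes of sulfate uptake and reduction rose with high SAM and 1 fell. MET17 (YLR303W, chromosome XII, 732542 to 733876 in R64), the O-acetylhomoserine sulfhydrylase that fixes sulfide into homocysteine, rose from 159.7 ± 18.8 to 922.4 ± 201 FPKM (n = 3, log2 fold change 2.51, adjusted p = 2.3e-05). MET17 overlaps YLR302C on the other strand, and the strand setting is not known. The ATP sulfurylase gene MET3 (YJR010W, chromosome X, 456239 to 457774) rose from 15.9 ± 1.54 to 115.9 ± 33.2 FPKM (n = 3, log2 fold change 2.75, adjusted p = 3.7e-05). The APS kinase gene MET14 rose from 37.8 ± 3.54 to 164.8 ± 27.6 FPKM (4.36-fold) and the PAPS reductase gene MET16 from 26.3 ± 1.89 to 86.0 ± 9.07 FPKM. Both sulfite reductase genes rose, MET10 from 35.0 ± 1.74 to 173.9 ± 43.3 FPKM (4.97-fold) and MET5 from 21.8 ± 2.60 to 83.3 ± 18.4 FPKM. MET1 and MET8, for the siroheme cofactor of that enzyme, rose by log2 fold changes of 1.20 and 1.38, and MET22, which degrades PAP, by 1.21. The sulfate permease genes moved apart. SUL2 rose from 27.2 ± 0.431 to 115.7 ± 45.5 FPKM, whereas SUL1 (YBR294W, chromosome II, 789235 to 791814) fell from 45.2 ± 9.73 to 14.6 ± 0.718 FPKM (log2 fold change -1.55, adjusted p = 0.00012). The list as a whole was higher (camera of limma, adjusted p = 0.00012, and adjusted p = 0.82 with an estimated correlation).

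All 7 genes of SAM synthesis and the methyl cycle rose in the bikaverin pair. The SAM synthetase genes were SAM1 (YLR180W, chromosome XII, 515262 to 516410), which rose from 149.3 ± 31.9 to 482.8 ± 55.1 FPKM (n = 3, 3.23-fold, adjusted p = 0.0001), and SAM2 (YDR502C, chromosome IV, 1453310 to 1454464), which rose from 134.6 ± 20.4 to 390.8 ± 64.2 FPKM (n = 3, 2.90-fold, adjusted p = 0.00015). The methionine synthase gene MET6 rose from 331.8 ± 10.9 to 676.5 ± 109 FPKM and the homocysteine methyltransferase gene SAM4 from 39.3 ± 8.58 to 98.2 ± 31.7 FPKM. SAH1, whose product hydrolyses the methylation by-product S-adenosylhomocysteine, rose from 398 ± 51.1 to 628.3 ± 187 FPKM (adjusted p = 0.03), and the adenosine kinase gene ADO1 from 130.7 ± 29.9 to 205.7 ± 35.4 FPKM (adjusted p = 0.018). The adjusted p of SAH1 rose above 0.05 when 1 library was left out (0.095, 0.093 and 0.054), as did that of ADO1 (0.051). The list was higher as a whole (list: adjusted p = 0.0060, and adjusted p = 0.82 with an estimated correlation).

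**Figure D1:**
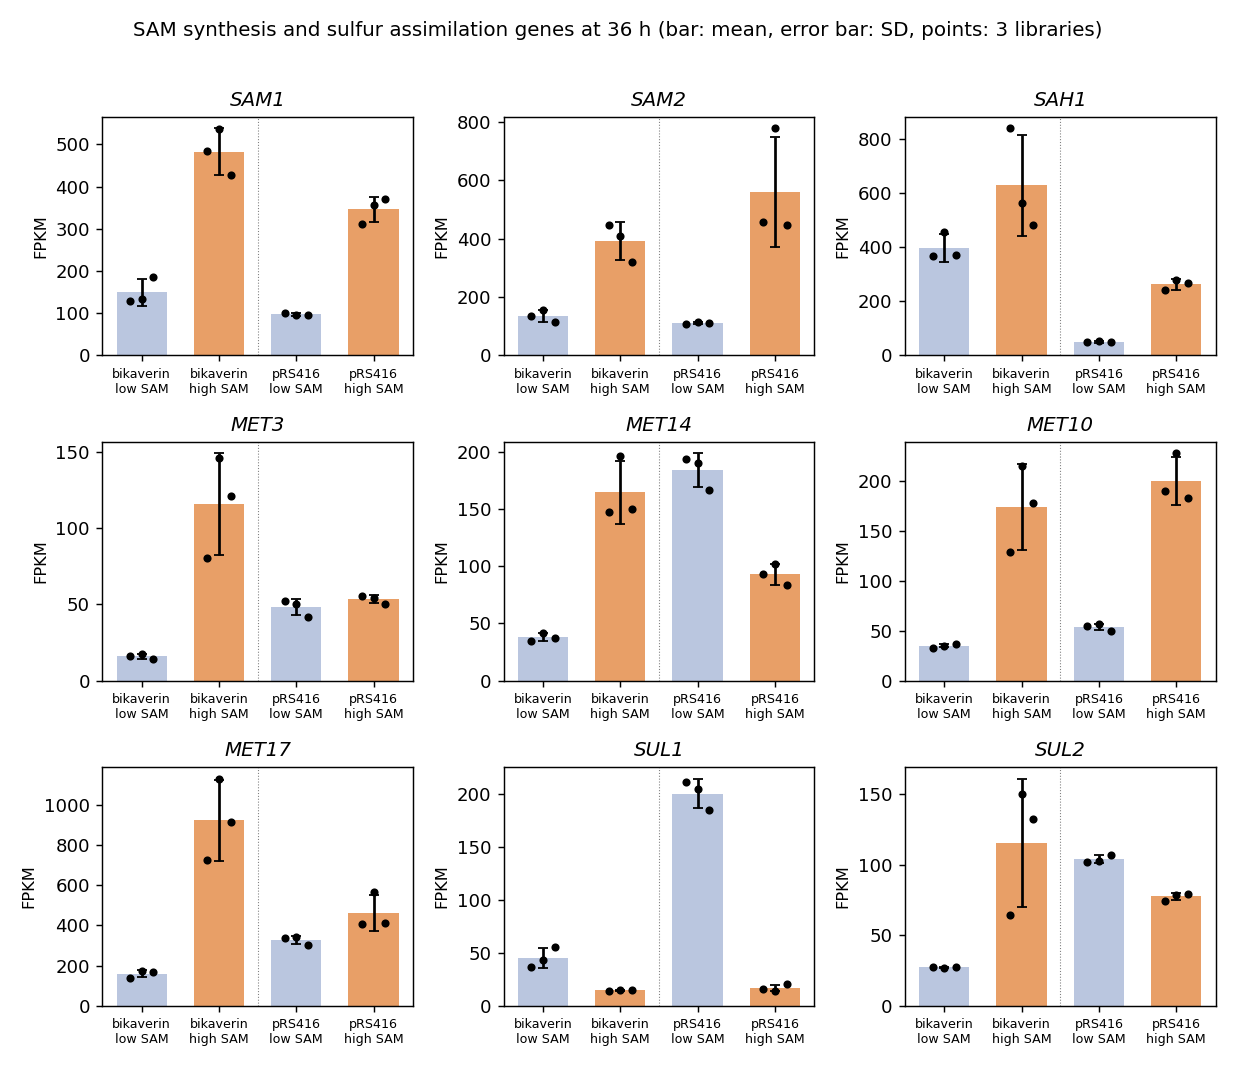
Levels of 9 genes of SAM synthesis, the methyl cycle and sulfate assimilation in the 4 groups, in FPKM. Bars are means, error bars are SD and points are the 3 libraries of a group; SAM1, for example, lay at 149.3 ± 31.9 and 482.8 ± 55.1 FPKM in the bikaverin pair and at 97.0 ± 2.97 and 345.8 ± 30.6 FPKM in the pRS416 pair.

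Further sulfur genes rose in the bikaverin pair without a call for their lists. Of 11 transsulfuration and glutathione genes 7 rose and 2 fell (adjusted p = 0.057). The glutathione reductase gene GLR1 (YPL091W) rose most, from 105.4 ± 9.11 to 1355 ± 53.1 FPKM (12.9-fold). The cystathionine gamma-lyase gene CYS3 rose from 51.9 ± 4.39 to 304.7 ± 23.0 FPKM and the glutamate-cysteine ligase gene GSH1 from 92.0 ± 8.53 to 261.6 ± 49.2 FPKM. Among 11 genes of sulfur amino acid transport and alternative sulfur sources 4 rose and 2 fell (adjusted p = 0.43). The methionine permease gene MUP1 rose from 97.7 ± 8.82 to 572.8 ± 78.7 FPKM and the SAM permease gene SAM3 from 136.8 ± 14.9 to 364.2 ± 25.3 FPKM. Of 27 SAM-dependent methyltransferase genes 13 rose and 7 fell (adjusted p = 0.27). The arginine methyltransferase gene HMT1 rose from 105.8 ± 17.9 to 290.6 ± 43.7 FPKM.

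Genes of protein synthesis and turnover also rose in the bikaverin pair. All 39 ribosome biogenesis genes rose. RRP12 went from 27.1 ± 1.75 to 77.6 ± 17.8 FPKM and RPA190, for the largest subunit of RNA polymerase I, from 26.7 ± 1.95 to 61.2 ± 9.74 FPKM (list: adjusted p = 1.6e-10, and adjusted p = 0.83 with an estimated correlation). Of 32 proteasome genes 27 rose and 0 fell, RPN1 from 128.1 ± 4.47 to 224.6 ± 16.2 FPKM (list: adjusted p = 5.0e-06, and adjusted p = 0.82 with an estimated correlation). Of 138 cytosolic ribosomal protein genes 48 rose and 10 fell, or 40 and 10 when adjusted over the list alone. RPL10 rose from 622.9 ± 69.7 to 1271 ± 53.5 FPKM, while RPS28B fell from 315.3 ± 23.6 to 53.4 ± 4.02 FPKM (list: adjusted p = 0.0034, and adjusted p = 0.93 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes 29 rose and 5 fell, or 27 and 4 when adjusted over the list alone, MRPL3 from 36.8 ± 1.63 to 81.3 ± 4.23 FPKM (list: adjusted p = 0.0032, and adjusted p = 0.83 with an estimated correlation). In the ergosterol and mevalonate pathway 11 of 25 genes rose and 14 were not past the threshold. The mevalonate pyrophosphate decarboxylase gene MVD1 rose from 49.96 ± 5.93 to 159 ± 23.1 FPKM (list: adjusted p = 0.0060, and adjusted p = 0.89 with an estimated correlation). Of 21 iron regulon genes 14 rose and 3 fell. The ferric reductase gene FRE1 rose from 63.96 ± 7.43 to 322.9 ± 41.5 FPKM. The ferroxidase gene FET3 rose from 93.4 ± 25.2 to 443.5 ± 39.6 FPKM and FRE3 fell from 63.9 ± 2.49 to 20.0 ± 0.895 FPKM (list: adjusted p = 0.021, and adjusted p = 0.83 with an estimated correlation).

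Genes of respiration and of the use of non-sugar carbon fell in the bikaverin pair. Of 16 beta-oxidation and peroxisome genes 15 fell and 0 rose. The acyl-CoA oxidase gene POX1 fell from 611.1 ± 5.46 to 61.5 ± 1.22 FPKM and the peroxisomal catalase gene CTA1 from 444.2 ± 16.8 to 37.3 ± 2.56 FPKM (list: adjusted p = 2.6e-09, and adjusted p = 0.82 with an estimated correlation). Of 15 genes of gluconeogenesis, the glyoxylate cycle and ethanol use 11 fell and 0 rose. The alcohol dehydrogenase gene ADH2 fell from 2033 ± 539 to 102 ± 15.2 FPKM (19.9-fold lower) and the malate synthase gene MLS1 from 1864 ± 113 to 377.7 ± 43.7 FPKM (list: adjusted p = 1.3e-05, and adjusted p = 0.82 with an estimated correlation). In the TCA cycle 13 of 15 genes fell. The aconitase gene ACO1 fell from 1719 ± 3.06 to 487.3 ± 24.2 FPKM and the citrate synthase gene CIT3 from 919.9 ± 160 to 69.2 ± 38.7 FPKM (list: adjusted p = 9.4e-05, and adjusted p = 0.45 with an estimated correlation). Among 32 genes of the respiratory chain and ATP synthase 27 fell and 2 rose, or 28 and 2 when adjusted over the list alone. COX7 fell from 835.7 ± 33.5 to 356.9 ± 21.2 FPKM (list: adjusted p = 5.1e-07, and adjusted p = 0.82 with an estimated correlation). The galactose permease gene GAL2 fell from 7072 ± 868 to 431.8 ± 91.6 FPKM, in a list of 18 hexose transport genes of which 11 fell and 4 rose, or 11 and 5 when adjusted over the list alone (adjusted p = 0.057).

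Stress, nitrogen and sporulation genes fell as well. Of 27 general stress genes 15 fell and 3 rose. RGI2 fell from 1445 ± 153 to 24.2 ± 3.11 FPKM and the cytosolic catalase gene CTT1 from 1449 ± 238 to 303.9 ± 68.4 FPKM. The vacuolar protease gene PRB1 rose from 1628 ± 94.3 to 4082 ± 214 FPKM (list: adjusted p = 0.0032, and adjusted p = 0.93 with an estimated correlation). Of 25 genes under nitrogen catabolite repression 15 fell and 4 rose, or 16 and 4 when adjusted over the list alone. The proline permease gene PUT4 fell from 347.8 ± 56.5 to 36.5 ± 11.014 FPKM (list: adjusted p = 0.011, and adjusted p = 0.82 with an estimated correlation). Of 15 sporulation genes 8 fell and 0 rose. The meiotic inducer gene IME1 fell from 85.9 ± 7.36 to 8.39 ± 0.678 FPKM (list: adjusted p = 0.032, and adjusted p = 0.83 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.073). All 4 alpha-mating-type genes rose. The pheromone gene MF(ALPHA)1 went from 378.4 ± 56.1 to 1221 ± 435 FPKM (list: adjusted p = 0.032, and adjusted p = 0.82 with an estimated correlation), a call lost without low-SAM replicate 3 (adjusted p = 0.053). Of 15 haploid-cell genes 9 rose and 1 fell, or 9 and 2 when adjusted over the list alone (adjusted p = 0.16), and of 7 a-mating-type genes 1 fell (adjusted p = 0.90).

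The largest rises of the bikaverin pair were in YAR068W, from 8.77 ± 2.52 to 623.6 ± 42.3 FPKM (71.1-fold, uncertain because of a copy of 99.8% identity), the hexose transporter gene HXT4, from 53.2 ± 34.0 to 2496 ± 504 FPKM (46.9-fold), and the copper transporter gene CTR3, from 11.4 ± 1.44 to 361.9 ± 20.8 FPKM (31.8-fold). They were followed by tY(GUA)J1, the polyamine exporter gene TPO2 (27.2 ± 5.47 to 575.1 ± 64.8 FPKM; uncertain because of its copy TPO3 of 90.8% identity), VBA3, THI11, THI4, PAU9 and LSO1, of which VBA3, THI11 and PAU9 are uncertain because of near-identical copies. The transfer RNA gene tY(GUA)J1 was not matched to the reference, so its copies were not checked and it is uncertain too. The thiazole synthase gene THI4 rose from 272.8 ± 255 to 5370 ± 4093 FPKM (log2 fold change 4.02, SE 1.011, adjusted p = 0.011). No read was seen in high SAM for the sulfatase gene BDS1 (YOL164W, chromosome XV, 6175 to 8115; 50.1 ± 0.871 FPKM in low SAM, at least 1556-fold lower), YOL164W-A (193.7 ± 56.5 FPKM in low SAM), YIL014C-A, YGR174W-A, TDA8 and YER138W-A, the last uncertain because its sequence has 73 other sites. UIP3 fell from 137.1 ± 8.68 FPKM to 1 read in 3 libraries (ratio 4668, exact 95% interval 838 to 184430), and YDL247W-A (not matched to the reference, and so uncertain), PRM8 and RGI2 complete the 10 largest falls.

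In all, 3662 of 6459 tested features (56.7%) were called in the bikaverin pair, 1863 higher and 1799 lower with high SAM, and 481 and 545 of these had a log2 fold change of at least 1 in size. The median log2 fold change was 0.01. Of 47 gene lists, 9 were called higher and 7 lower by camera of limma, where 19 had an unadjusted p below 0.05. With an estimated correlation between genes 0 of the 16 calls were kept, a loss that cannot be put down to that correlation alone, as set out below. Counts of member genes are descriptions, which do not allow for that correlation, and 56.7% of all features were called. Counts adjusted over the list alone equalled those over all genes where none is given.

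In the pRS416 pair, the SAM synthetase genes rose again while most genes of sulfate uptake and reduction fell. SAM1 rose from 97.0 ± 2.97 to 345.8 ± 30.6 FPKM (n = 3, 3.57-fold, adjusted p = 5.0e-08) and SAM2 from 111.1 ± 2.82 to 559.8 ± 188 FPKM (n = 3, 5.04-fold, adjusted p = 3.5e-06). SAH1 rose from 50.5 ± 2.83 to 262.1 ± 19.1 FPKM (5.19-fold) and ADO1 from 50.7 ± 2.74 to 118.5 ± 11.6 FPKM (2.33-fold), while the methionine synthase gene MET6 fell from 448.3 ± 16.2 to 328.8 ± 7.15 FPKM. In that list 5 of 7 genes rose and 2 fell (adjusted p = 0.16). Of the 11 genes of sulfate uptake and reduction 7 fell, 2 rose and 2 were not past the threshold (adjusted p = 0.27). SUL1 fell from 200.4 ± 14.1 to 16.7 ± 3.03 FPKM (log2 fold change -3.52, adjusted p = 9.9e-09), SUL2 from 103.9 ± 2.77 to 77.6 ± 2.58 FPKM, MET14 from 184 ± 14.8 to 92.9 ± 9.06 FPKM and MET5 from 83.1 ± 4.27 to 39.5 ± 2.15 FPKM. MET1 and MET8 fell by log2 fold changes of -0.50 and -0.61, and MET16 fell from 67.0 ± 2.18 to 52.4 ± 11.8 FPKM (adjusted p = 0.028), a call lost in 5 of 6 fits without 1 library (adjusted p = 0.058 to 0.10). MET10 rose from 53.8 ± 3.39 to 200.2 ± 24.2 FPKM (3.72-fold) and MET17 from 328 ± 21.0 to 460.1 ± 89.9 FPKM (adjusted p = 0.0071). MET3 (48.1 ± 5.37 and 53.4 ± 2.60 FPKM, adjusted p = 0.14) and MET22 (log2 fold change 0.05, adjusted p = 0.46) were not past the threshold.

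Other sulfur genes of the pRS416 pair moved both ways. GLR1 rose from 77.4 ± 2.01 to 1782 ± 110 FPKM (23.0-fold) and CYS3 from 54.8 ± 3.28 to 150.5 ± 17.9 FPKM, while the cystathionine beta-synthase gene CYS4 fell from 385.2 ± 5.83 to 210.8 ± 3.71 FPKM. Among the 11 transsulfuration and glutathione genes 6 rose and 2 fell (adjusted p = 0.27). Of 11 sulfur transport genes 7 fell and 2 rose, or 7 and 3 when adjusted over the list alone (adjusted p = 0.094). The sulfonate dioxygenase gene JLP1 fell from 172.8 ± 2.90 to 33.6 ± 2.70 FPKM and the cysteine transporter gene YCT1 from 99.2 ± 5.13 to 18.1 ± 2.16 FPKM. BDS1 fell from 60.5 ± 1.60 FPKM to 2 reads in 3 libraries (ratio 7481, exact 95% interval 2071 to 61781). BDS1 is among the features near 0 in high SAM of both pairs, and a missing or diverged stretch of the genome stays open for it, as set out below. Of 27 methyltransferase genes 13 rose and 11 fell (adjusted p = 0.77).

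Respiratory genes rose throughout in the pRS416 pair. All 32 genes of the respiratory chain and ATP synthase rose. Among them were the cytochrome c genes CYC1, from 28.7 ± 1.21 to 1059 ± 96.6 FPKM (36.9-fold), and CYC7, from 88.8 ± 2.03 to 2141 ± 341 FPKM (24.1-fold). The NADH dehydrogenase gene NDE1 rose from 164.4 ± 1.98 to 2312 ± 422 FPKM (list: adjusted p = 5.3e-11, and adjusted p = 0.77 with an estimated correlation). In the TCA cycle 14 of 15 genes rose. The isocitrate dehydrogenase genes rose, IDH1 from 117.1 ± 2.75 to 2297 ± 291 FPKM and IDH2 from 68.0 ± 2.97 to 1339 ± 132 FPKM, while CIT3 fell from 582.7 ± 12.2 to 66.1 ± 5.36 FPKM (list: adjusted p = 0.00011, and adjusted p = 0.77 with an estimated correlation). Of 21 iron regulon genes 18 rose and 3 fell. The heme oxygenase gene HMX1 rose from 17.7 ± 1.11 to 451.8 ± 50.9 FPKM and FET3 from 39.7 ± 0.723 to 815.4 ± 106 FPKM (list: adjusted p = 5.8e-05, and adjusted p = 0.77 with an estimated correlation). Heat shock genes rose in 16 of 21 cases and fell in 2, the mitochondrial chaperone gene HSP78 from 283 ± 8.64 to 1635 ± 77.5 FPKM (list: adjusted p = 0.0035, and adjusted p = 0.82 with an estimated correlation). In the ergosterol pathway 17 of 25 genes rose and 3 fell, ERG3 from 165.4 ± 7.73 to 1530 ± 73.3 FPKM (list: adjusted p = 0.010, and adjusted p = 0.82 with an estimated correlation). Of 39 ribosome biogenesis genes 28 rose and 4 fell, NOP58 from 31.9 ± 0.422 to 95.2 ± 5.55 FPKM (list: adjusted p = 0.0013, and adjusted p = 0.82 with an estimated correlation).

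Genes that mark haploid cells and cells of mating type alpha fell in the pRS416 pair. All 15 haploid-cell and pheromone response genes fell. The G protein genes were among them, STE4 from 202.3 ± 6.42 to 9.19 ± 0.774 FPKM (22.0-fold lower), STE18 from 100.8 ± 3.97 to 2.20 ± 0.649 FPKM (45.9-fold lower) and GPA1 from 79.2 ± 2.61 to 13.4 ± 0.195 FPKM (list: adjusted p = 1.6e-05, and adjusted p = 0.28 with an estimated correlation). All 4 alpha-mating-type genes fell. MF(ALPHA)1 went from 707.1 ± 29.7 to 3.68 ± 0.583 FPKM (192-fold lower) and the a-factor receptor gene STE3 from 110.1 ± 5.83 to 11.8 ± 1.41 FPKM (list: adjusted p = 0.0099, and adjusted p = 0.77 with an estimated correlation). HMRA1 (YCR097W, chromosome III, 293835 to 294321), a copy of the mating-type gene a1, stood at 2 reads in the 3 low-SAM libraries and at 117.3 ± 31.0 FPKM in high SAM (ratio 2890, exact 95% interval 800 to 23867). Of 7 a-mating-type genes 4 fell and 2 rose. The pheromone gene MFA1 fell from 60.1 ± 1.26 to 36.5 ± 5.73 FPKM and the protease gene BAR1 rose from 4.67 ± 0.923 to 9.64 ± 1.0095 FPKM (list: adjusted p = 0.57). Of 15 sporulation genes 12 fell and 1 rose, SPS100 from 5476 ± 25.4 to 52.9 ± 7.66 FPKM (list: adjusted p = 0.0050, and adjusted p = 0.55 with an estimated correlation).

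Fat, stress and nitrogen genes fell in the pRS416 pair too. Of 16 beta-oxidation genes 13 fell and 2 rose. POX1 fell from 451.5 ± 11.02 to 57.3 ± 4.21 FPKM and the enoyl-CoA isomerase gene ECI1 from 269.2 ± 12.998 to 31.2 ± 1.81 FPKM (list: adjusted p = 0.00026, and adjusted p = 0.77 with an estimated correlation). Of 26 general stress genes 20 fell and 6 rose. RGI2 fell from 1541 ± 98.8 to 120.4 ± 11.5 FPKM and the aldehyde dehydrogenase gene ALD3 (uncertain because of a copy of 91.8% identity) from 1866 ± 50.2 to 252.9 ± 20.9 FPKM (list: adjusted p = 0.0083, and adjusted p = 0.82 with an estimated correlation). Of 25 genes under nitrogen catabolite repression 16 fell and 6 rose. PUT4 fell from 294.7 ± 33.8 to 4.21 ± 0.783 FPKM (70.0-fold lower) and the repressor gene DAL80 from 23.6 ± 1.45 to 0.484 ± 0.0748 FPKM (list: adjusted p = 0.038, and adjusted p = 0.77 with an estimated correlation). That call was lost without high-SAM replicate 2 (adjusted p = 0.057) and with a filter of 10 FPKM (adjusted p = 0.055). Genes of gluconeogenesis and ethanol use split, 9 rising and 6 falling of 15. The phosphoenolpyruvate carboxykinase gene PCK1 rose from 162.3 ± 12.9 to 2489 ± 195 FPKM, while the acetate transporter gene ADY2 fell from 1147 ± 111 to 12.8 ± 1.29 FPKM. The median log2 fold change of this list was 0.91 and its mean -0.29, and the test leaned upwards (adjusted p = 0.69). In the galactose regulon 6 of 10 genes fell and 3 rose. GAL2 fell from 2983 ± 120 to 74.0 ± 1.41 FPKM and GAL1 from 1798 ± 6.14 to 236.7 ± 27.1 FPKM (list: adjusted p = 0.17).

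The largest rises of the pRS416 pair were in the cell wall gene CIS3, from 5.27 ± 0.476 to 820.9 ± 143 FPKM (156-fold), HXT4, from 29.3 ± 0.747 to 3405 ± 305 FPKM (116-fold), HMRA1, SCW10, from 17.7 ± 0.796 to 1635 ± 140 FPKM (92.6-fold), and the cyclin gene PCL1, from 6.05 ± 1.27 to 584.6 ± 52.1 FPKM (96.6-fold). HSP30, TPO2 (uncertain because of its copy TPO3), TOS6, CYC1 and YGR139W (uncertain, as it was not matched to the reference) followed, with HSP30 up from 192.5 ± 8.49 to 12733 ± 3132 FPKM. Among the largest falls, the cell wall gene TIP1 went from 3022 ± 69.4 to 14.0 ± 0.316 FPKM (216-fold lower), YCL048W-A from 1595 ± 127 to 7.95 ± 2.08 FPKM (201-fold lower) and SPS100 was 103-fold lower. MF(ALPHA)1, YOL164W-A, YIL014C-A, ADY2, UIP3 and the unmatched and uncertain YDL247W-A and tN(GUU)P were the others, and no read of YOL164W-A (at least 1006-fold lower) or YIL014C-A (at least 1244-fold lower) was seen in high SAM.

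**Figure D2:**
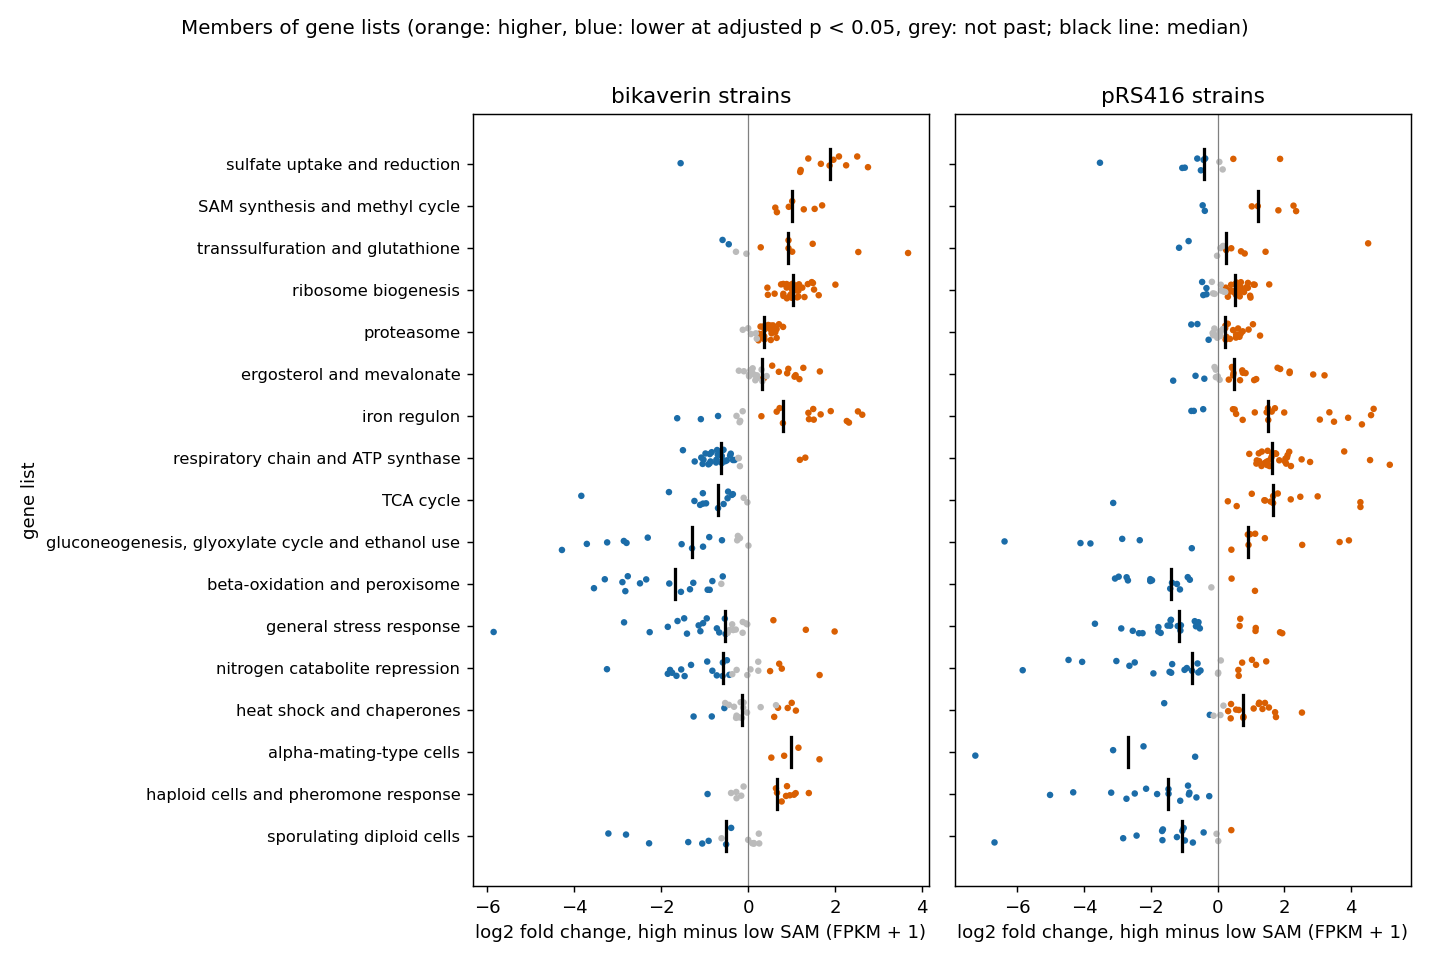
Members of 17 gene lists in each pair, as log2 fold change of high against low SAM. Each point is a gene, orange where called higher, blue where called lower and grey where not past the threshold, and black lines are medians (1.62 for the respiratory list in the pRS416 pair, -0.63 in the bikaverin pair).

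Altogether 4918 of 6342 features (77.5%) were called in the pRS416 pair, 2481 higher and 2437 lower, with 880 and 803 at a log2 fold change of at least 1 in size. The median log2 fold change was -0.01. Camera of limma called 6 lists higher and 6 lower of 47, where 16 had an unadjusted p below 0.05, and 0 with an estimated correlation. List-alone counts of this pair equalled those over all genes where none is given.

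The pairs were then compared to see which changes were shared by both. Neither the genetic change behind high SAM nor whether strains of like SAM level share a parent is given in the sources used here, so a shared change cannot be assigned to SAM rather than to the strains. SAM1, SAM2, SAH1, ADO1, MET10, MET17, GLR1 and CYS3 rose in both, and SUL1 fell in both. TIP1, lower in both, fell from 5269 ± 825 to 144.6 ± 69.9 FPKM in the bikaverin pair. By the smaller of the 2 changes, the 10 genes of largest shared change were YOL164W-A, YDL247W-A, YIL014C-A, UIP3, YER138W-A, BDS1, HXT4, tN(GUU)P, TIP1 and YOL163W, of which only HXT4 rose. YER138W-A has near-identical copies and is uncertain, as are YDL247W-A and the transfer RNA gene tN(GUU)P, whose copies were not checked because they were not matched to the reference. YOL163W, next to BDS1 on chromosome XV, had no read in high SAM of either pair (at least 249-fold and 1018-fold lower). Of 6268 genes tested in both pairs, 1189 were higher in both against 718.8 in independent lists (Fisher's exact test, one-sided for more overlap, odds ratio 4.61, p = 3.2e-156) and 1196 were lower in both against 674.2 (odds ratio 5.81, exact p = 6.7e-198). The opposite calls numbered 261 and 294, fewer than the 701.0 and 691.3 of independent lists, a deficit that the test did not address. Fisher's exact test takes genes as independent of each other, which they are not, so its p-values overstate the evidence for a shared change. Pearson's r between the fold changes was 0.59 and Spearman's rho 0.51, as a description across genes, and 68.2% of genes had the same sign.

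**Figure D3:**
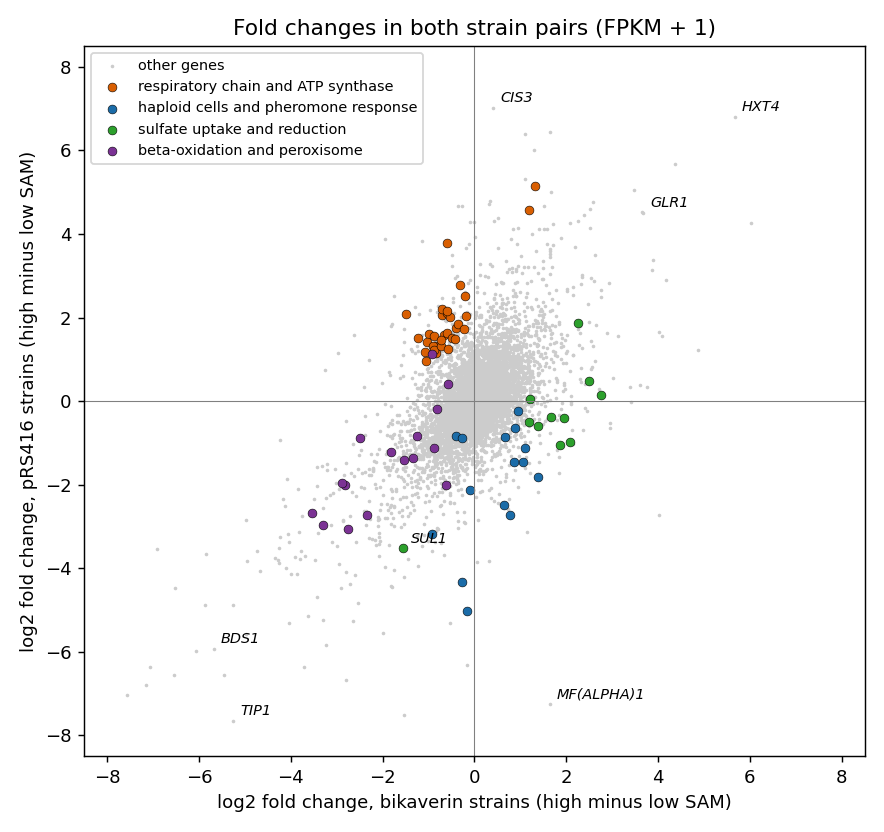
Log2 fold change of high against low SAM in the bikaverin pair (x axis) and in the pRS416 pair (y axis), 1 point per gene (r = 0.59). Genes of the respiratory chain are orange, of haploid cells blue, of sulfate assimilation green and of beta-oxidation purple, and CIS3, HXT4, GLR1, SUL1, BDS1, TIP1 and MF(ALPHA)1 are labelled.

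The difference between the pairs was tested to see which changes between high-SAM and low-SAM strains differed between the pairs. Each SAM level of a pair is 1 strain, and each pair has its own table. A difference therefore cannot be assigned to SAM rather than to the strains or to a batch. Values are log2 differences, bikaverin pair minus pRS416 pair. Genes of sulfate uptake and reduction were higher in the bikaverin pair relative to the pRS416 pair in 10 of 11 cases, all but MET10 (0.38, adjusted p = 0.14). MET14 differed by 3.07, MET5 by 2.93, MET3 by 2.60, SUL2 by 2.38, MET16 by 2.04, MET17 by 2.03, MET8 by 1.99, SUL1 by 1.97, MET1 by 1.70 and MET22 by 1.15. Its list had a mean of 2.02 (list: adjusted p = 1.4e-06, and adjusted p = 0.53 with an estimated correlation). SAM1 did not differ past the threshold (-0.12, adjusted p = 0.61), nor did ADO1 (-0.54, adjusted p = 0.053), while SAM2 (-0.74, adjusted p = 0.034) and SAH1 (-1.73) rose less in the bikaverin pair and MET6 differed by 1.46. Of the 11 sulfur transport genes 8 were higher and 1 lower, MUP1 by 1.76 and the glutamine permease gene GNP1 by 4.14 (list: adjusted p = 0.0040, and adjusted p = 0.53 with an estimated correlation).

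Respiration gave the opposite picture, with all 32 respiratory genes lower in the bikaverin pair relative to the pRS416 pair, by a mean of -2.52 (list: adjusted p = 6.8e-22, and adjusted p = 0.28 with an estimated correlation), CYC1 by -3.84. In the TCA cycle 14 of 15 genes were lower (list: adjusted p = 5.4e-11, and adjusted p = 0.11 with an estimated correlation). Iron genes were lower in 14 of 21 cases and higher in 2, FET3 by -2.05 (list: adjusted p = 0.0014, and adjusted p = 0.62 with an estimated correlation). Gluconeogenesis genes were lower in 11 of 15 cases and higher in 2 (list: adjusted p = 0.00069, and adjusted p = 0.53 with an estimated correlation). Of 16 trehalose and glycogen genes 12 were lower and 1 higher (list: adjusted p = 0.011, and adjusted p = 0.76 with an estimated correlation). Among 21 heat shock genes 12 were lower and 1 higher, or 13 and 1 when adjusted over the list alone (list: adjusted p = 0.0040, and adjusted p = 0.76 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.051). Beta-oxidation genes were lower in 10 of 16 cases and higher in 3 (list: adjusted p = 0.045, and adjusted p = 0.76 with an estimated correlation), a call lost in several alternatives (adjusted p = 0.051 to 0.090).

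Haploid-cell genes were higher in 14 of 15 cases, or 15 when adjusted over the list alone, by a mean of 2.36 (list: adjusted p = 4.9e-10, and adjusted p = 0.28 with an estimated correlation), and all 4 alpha-mating-type genes by a mean of 4.35 (list: adjusted p = 0.00027, and adjusted p = 0.37 with an estimated correlation). Ribosome biogenesis genes were higher in 22 of 39 cases and lower in 0, or 24 and 0 when adjusted over the list alone (list: adjusted p = 0.00014, and adjusted p = 0.76 with an estimated correlation). Of 138 cytosolic ribosomal protein genes 42 were higher and 8 lower, or 34 and 6 when adjusted over the list alone (list: adjusted p = 0.012, and adjusted p = 0.92 with an estimated correlation). That call was lost without bikaverin low-SAM replicate 1 (adjusted p = 0.056), bikaverin high-SAM replicate 1 (adjusted p = 0.076) or pRS416 high-SAM replicate 2 (adjusted p = 0.076). Of all genes, MF(ALPHA)1 (8.89), THI4 (6.76), YDL218W (6.17), YCL048W-A (5.97) and STE18 (4.86) differed most upwards, and CIS3 (-6.61), ZRT1 (-5.81), HMRA1 (-5.80), PCL1 (-5.29) and the small nucleolar RNA snR30 (-5.02; not matched to the reference and uncertain) most downwards. The zinc transporter gene ZRT1 fell from 2889 ± 162 to 752.6 ± 68.9 FPKM in the bikaverin pair and rose from 51.9 ± 1.24 to 776.7 ± 90.6 FPKM in the pRS416 pair. In all, 3636 of 6400 features (56.8%) differed, 1779 higher and 1857 lower, 584 and 694 of them by a log2 difference of at least 1. On the recovered reads (limma voom), 57.2% of the calls were higher against 48.9% here. Camera of limma called 6 lists higher and 7 lower, where 16 had an unadjusted p below 0.05, and 0 with an estimated correlation. Here too, list-alone counts equalled those over all genes where none is given.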

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

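The gene tests within the pairs and of their difference were planned, and all other tests in this part were chosen after the results had been seen. The values below are log2 differences, bikaverin pair minus pRS416 pair, unless said otherwise. A gene list or gene is given here because the change with high SAM differed between the pairs, and the module features because they carried a signal in data on which nothing was reported. Mean differences were 2.02 for sulfate uptake and reduction, 1.50 for sulfur amino acid transport and alternative sulfur sources, 4.35 for alpha-mating-type cells, 2.36 for haploid cells, 0.61 for ribosome biogenesis and 0.20 for cytosolic ribosomal proteins. They were -2.52 for the respiratory chain and ATP synthase, -2.57 for the TCA cycle, -1.39 for gluconeogenesis and ethanol use, -1.01 for the iron regulon, -0.76 for heat shock genes, -0.69 for trehalose and glycogen and -0.44 for beta-oxidation. When the libraries were regrouped, 38 of 100 splits called at least as many lists (13 in the real groups, up to 22 in others) and 1 of 100 reached the real count of genes (3636, up to 2854 in others). Neither decides whether chance played a part, because each wrong grouping keeps part of the real contrast, and splits with both pairs wrongly grouped called 0 genes.

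By gene, the differences were 8.89 for MF(ALPHA)1, 6.76 for the thiamine gene THI4, 6.17 for YDL218W, 5.97 for YCL048W-A and 4.86 for STE18. They were -6.61 for the cell wall gene CIS3, -5.81 for the zinc transporter gene ZRT1, -5.80 for HMRA1, -5.29 for the cyclin gene PCL1 and -5.02 for snR30. CIS3 (log2 fold change 0.41, adjusted p = 0.098), STE18 (-0.16, adjusted p = 0.15) and YDL218W (-0.15, adjusted p = 0.68) were called in the pRS416 pair alone, while THI4 (4.02 and -2.73), ZRT1 (-1.94 and 3.87) and MF(ALPHA)1 (1.64 and -7.25) were called in opposite directions. Features of the bikaverin module are listed in the pRS416 table, where their highest values, all in high-SAM replicate 1, were 0.177 FPKM for BIK1, 0.361 for BIK23, 0.0339 for BIK3, 0.505 for BIK6, 1.24 for NPGA and 1.26 for PPT. PPT also stood at 0.805 FPKM in low-SAM replicate 1 and NPGA at 0.538 FPKM in high-SAM replicate 3, and the cause, such as carry-over between samples or libraries, was not tested. These features were not among those of the bikaverin table used here.

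The fall of haploid and alpha-type genes in the pRS416 pair was weighed against 3 explanations. Cells of mating type a in the high-SAM samples would raise a-specific genes, but their median log2 fold change was -0.35, which argues against it. Scaling was excluded, since the mean of the haploid list stayed at -1.92 or further from 0 under both other scalings. Repression of haploid genes by the a1-alpha2 repressor in strain YJ-09, as in cells that hold both mating types, stays open, since the fall of all 15 haploid genes and the rise of HMRA1 to 117.3 FPKM raised this explanation and so do not test it. The alpha genes of the mating-type locus have identical copies and could not be read, so the genotype of YJ-09 was not tested.

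Respiratory genes fell in the bikaverin pair and rose in the pRS416 pair. Scaling was excluded, as the mean difference stayed at -2.23 or further from 0. The tables differ in depth by a factor of 2.60, and a difference between them in growth, library or sequencing batch cannot be told apart from the strains. The level of HAP4, the activator of respiratory genes (chosen after its values were seen), differed by -4.97, falling from 280.8 ± 21.1 to 125.8 ± 6.83 FPKM in the bikaverin pair and rising from 104.8 ± 9.10 to 1512 ± 307 FPKM in the pRS416 pair. Because it was picked for these values, they leave its part in the pattern open.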

How the results depend on the processing

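No named gene or list past the threshold changed direction under any alternative. The balance of calls did move: in the difference 48.9% were higher, against 52.0% with quantile normalization and 57.2% with limma voom, and in the pRS416 pair 50.4%, against 49.2% and 46.1%. With 1 library left out, calls ranged from 3050 to 3618 (bikaverin), 4570 to 4940 (pRS416) and 3285 to 3625 (difference), shared calls from 2042 to 2404, r from 0.583 to 0.597, and list calls from 15 to 18, 11 to 13 and 11 to 15. Over the other settings calls ranged from 3394 to 4098, 4481 to 5025 and 3396 to 3651, shared calls from 2206 to 2404, and list calls, at the preset correlation, from 15 to 17, 11 to 13 and 12 to 16. Between the pairs, r was 0.62 and 0.57 with pseudocounts of 0.1 and 5, 0.58 with no filter, 0.64 with limma voom on recovered reads and 0.56 without the 20 features near 0 in both pairs, and the cause was not tested. Requiring a log2 fold change of at least 1 in size left 1026, 1683 and 1278 calls by construction. Camera of limma with an estimated correlation called 0, 0 and 0 lists. The TCA list of the bikaverin pair lost its call (camera of limma, adjusted p = 0.45) at an estimated correlation of -0.0087, below the preset 0.01. A larger correlation between genes therefore does not account for that loss, and the cause was not tested. Calls of other lists lost in this setting thus cannot be put down to correlation between genes alone. With a replicate block there were 3506, 4815 and 3445 calls of genes, against 3662, 4918 and 3636 without it. Among the named genes and the lists it ended 1 call, that of beta-oxidation in the difference (adjusted p = 0.0895). It added calls for hexose transport (adjusted p = 0.037), LYS9 (adjusted p = 0.023) and MFA2 (adjusted p = 0.030) in the bikaverin pair, mitochondrial ribosomal proteins in the pRS416 pair (adjusted p = 0.047) and marker genes in the difference (adjusted p = 0.044), and changed no other call of a named gene or list. Same-number correlations were 0.03, -0.08 and 0.12 in the bikaverin pair and -0.13, -0.03 and -0.14 in the pRS416 pair. Not every sample correlated best with its own number, so these values do not show that the numbers pair the libraries. With 3 such values per pair, pairing cannot be excluded either. Among named genes 18 calls were lost in some setting (7 genes) and 9 gained (5 genes), and among list calls at the preset correlation 16 were lost (6 lists) and 26 gained (9 lists); the cause was not tested. Regrouping the 6 libraries of a pair gives 10 splits, too few for a share under 0.05: 1 of 10 reached the real gene calls (bikaverin 3662, highest other 0; pRS416 4918, highest other 0), while 6 and 5 of 10 reached the real list calls (16, highest other 19; 12, highest other 16). For shared calls 1 of 100 splits reached the real count (2385, highest other 0), which decides nothing, because every wrong grouping of a pair called 0 genes. For r, 1 of 100 splits reached the real value (0.59, highest other 0.58), which decides nothing either, because each wrong grouping of 3 and 3 keeps 2 of 3 libraries together and so part of the real contrast. Depth limits genes of 1 kb below about 0.195 FPKM (bikaverin) and 0.0737 FPKM (pRS416) to fewer than 3 reads per library, and tests on counts from the authors were not run.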

Other observations

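The list tests within each pair were fixed in advance. Of the tests on features near 0 in this part, only that for near-identical copies was fixed before its values were seen. Single genes of further groups changed in the pRS416 pair, and none of these lists was called. Of 24 cell cycle and histone genes 14 rose and 5 fell (adjusted p = 0.094), the G1 cyclin genes CLN1 from 13.4 ± 1.23 to 250.2 ± 23.8 FPKM and CLN2 from 21.0 ± 1.75 to 223.9 ± 23.7 FPKM, and the ribonucleotide reductase gene RNR1 from 6.84 ± 0.594 to 199.8 ± 37.4 FPKM (29.2-fold). Of 26 cell wall genes 11 rose and 13 fell (adjusted p = 0.98), the glucan synthase gene FKS1 up from 38.7 ± 1.7995 to 361.4 ± 13.02 FPKM and CRH1 up from 126.9 ± 4.80 to 1157 ± 94.9 FPKM. In the pentose phosphate and NADPH group 6 of 17 genes rose and 7 fell (adjusted p = 0.69), the transketolase gene TKL1 up from 17.7 ± 0.657 to 324.9 ± 43.6 FPKM and the glutamate dehydrogenase gene GDH3 down from 2227 ± 123 to 250.0 ± 26.4 FPKM. Of 14 unfolded protein response genes 8 rose and 4 fell (adjusted p = 0.31), the regulator gene HAC1 from 159.3 ± 5.24 to 662.3 ± 112 FPKM.

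Single genes of other groups changed in both pairs, again with no list called. The mitochondrial transaminase gene BAT1 rose from 148.9 ± 17.6 to 542.8 ± 119 FPKM in the bikaverin pair and from 93.5 ± 1.83 to 353.8 ± 55.3 FPKM in the pRS416 pair, while its cytosolic counterpart BAT2 fell from 768.2 ± 71.0 to 101.6 ± 15.6 FPKM and from 324.2 ± 22.4 to 86.2 ± 9.67 FPKM. Of 11 genes of branched-chain amino acid synthesis 4 rose and 2 fell in the bikaverin pair (adjusted p = 0.88) and 9 rose and 2 fell in the pRS416 pair (adjusted p = 0.16). The biotin synthesis gene BIO4 rose from 218.2 ± 25.5 to 717.1 ± 9.88 FPKM and from 25.3 ± 1.51 to 508.3 ± 135 FPKM, in a list of 26 thiamine, biotin and NAD genes that split both times (14 up and 8 down, or 14 and 10 adjusted over the list alone, adjusted p = 0.315; 10 up and 12 down, adjusted p = 0.69). The weak-acid exporter gene PDR12 fell from 1737 ± 146 to 160.3 ± 11.6 FPKM and from 388.1 ± 20.9 to 94.9 ± 4.87 FPKM. The old yellow enzyme gene OYE2 rose from 358.9 ± 50.9 to 1775 ± 235 FPKM and from 87.3 ± 4.17 to 305.7 ± 19.6 FPKM. The invertase gene SUC2, chosen after its values were seen, rose from 86.0 ± 6.62 to 448.2 ± 86.9 FPKM and from 27.3 ± 2.10 to 230.3 ± 17.7 FPKM.

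In the high-SAM libraries 31 features (bikaverin) and 34 (pRS416) had a mean below 0.5 FPKM while their mean in low SAM was at least 5 FPKM, and 20 were so in both pairs, against 0.156 in independent lists of 6755 features (Fisher's exact test, p = 7.4e-42). That p-value takes features as independent of each other, which neighbours on a chromosome may not be. The reverse was seen for 2 features, VBA3 and GEX1 (chosen after their values were seen), which have near-identical copies. They lie within 10 kb of each other on chromosome III (9706 to 11082 and 6479 to 8326). The test for neighbours given below was not run in this direction. At most 0.0447% of the reads that the low-SAM level predicts were seen in high SAM. The selection of these features alone keeps that share below about 10%, so it does not test lower depth. Scaling totals of the high-SAM libraries were 15.4 to 16.8 M (bikaverin) and 40.7 to 43.5 M (pRS416). Those of the low-SAM libraries were 16.4 to 17.7 M and 42.1 to 45.1 M, and such near-equal depths argue against it. Reads shared with near-identical copies account at most for the 5 of 14 features (those with coordinates) that have a second site (YAR064W, YER138W-A, YER188C-A, YHR213W-B and YOR192C-C), and 9 had none. Stretches missing from, or diverged in, the genome of the high-SAM strains predict that such features lie together, and 4 had a neighbour of the set within 10 kb (BDS1, YOL162W, YOL163W and YOL164W-A, chromosome XV, 4130 to 10766), against a median of 0 and a highest value of 6 in 10000 random sets (permutation p = 0.0098). The test was chosen after the values were seen, its 4 features form a single stretch, and the random sets were not matched for position. So a shared missing or diverged stretch near that chromosome end stays open for these 4. The genome sequence of the strains, not analysed here, would settle it. The other features without a second site, TDA8, YAR035C-A, YCL021W-A, YIL014C-A and OST2, had no neighbour of the set, and the cause of their loss was not tested. Features of the set without coordinates could not count as neighbours. UIP3 (chromosome I, 183770 to 184477), lower in both pairs but outside the set, lies within 10 kb of YAR035C-A (192337 to 192417).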
